A study of Mus musculus with 6 samples.

How the data were processed

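RNA was measured in whole lungs of BALB/c mice, an inbred laboratory strain, for which the labels give an age of 9 weeks. PM2.5 is airborne particulate matter of up to 2.5 µm across. Per the labels' protocols, mice received either 50 µl of saline or the same volume holding PM2.5 at 5 mg per kg of body weight through the trachea, weekly for 8 weeks. RNA was extracted with Trizol and 2 µg of it entered a NEBNext Ultra library kit, which does not mark the strand. The design holds 6 libraries, 3 from saline lungs and 3 from PM2.5 lungs, both numbered 2, 3 and 4. The labels do not say that the libraries of a group came from separate mice, so the p-values measure the spread between these samples, whatever its source.

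The deposited table held a single value per transcript and library, read here as FPKM (mapped fragments scaled to transcript length and library size). Its header named no unit, and FPKM was inferred from the values: the columns summed to between 345089 and 388125, and low values multiplied by transcript span fell near regular steps. Per the submitters' processing notes, bcl2fastq, HISAT2 and the genome build mm10 were used, with versions not given. The quantifier and the annotation release are not given in the sources used here. Of the transcripts listed, 70782 carried Ensembl identifiers, 66167 carried identifiers of NONCODE, a database of noncoding RNA, and 12779 carried identifiers starting with MERGE, with no position and no gene. MERGE transcripts held 17.6% to 20.6% of the FPKM of a library and could be assigned to no gene, so a gene's value leaves out any fragments counted there. Circular RNA was not analysed here.

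The number of fragments behind each value is not stated. The spacing of low values of transcripts spanning 1500 to 3000 bases corresponded to 18.8 to 22.1 M fragments per library. This is an estimate, since 36.4% to 39.3% of those values lay within 0.05 of a whole step, and no counts were recovered from it. At that depth, 3 fragments on a transcript of 1 kb correspond to 0.136 to 0.159 FPKM, which covers counting error only. A value of exactly 0 can be a failed estimate, so it is reported as listed at 0, with the value of each library.

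FPKM of Ensembl transcripts were summed per gene symbol, which gave 22158 genes. Genes, and in a separate fit all transcripts, with a mean of at least 0.5 FPKM over the 6 libraries were compared as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3. The fit used empirical Bayes moderation with a mean trend, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are on the log2(FPKM + 0.5) scale, PM2.5 over saline, and understate the change of genes with low values. Long noncoding RNAs were the NONCODE transcripts that the table describes as lncRNA, taken from the transcript fit. A gene table of assembly GRCm38.p6 served only for older gene names and gene classes, and coordinates are those of the deposited table. Overlaps between transcripts and genes were computed with GenomicRanges 1.54.1, and tables were read with version 1.17.8 of data.table.

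Of 54 gene lists for pathways, cell types and technical checks, 51 had at least 3 tested members and were compared with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run as alternatives. Members were also adjusted over their list alone, which makes no correction for the number of lists. The lists hold 831 names, of which 784 were found by symbol, 12 by an older name and 35 were not found. The fit, the threshold, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule, the text names up to 12 genes per direction with the largest changes past the threshold, with no overlap between groups and at least 1 FPKM in a group. Places left over were filled by the lowest unadjusted p, and predicted genes without a proper symbol were left out. It also names up to 4 members with the lowest p of each list past the camera threshold, up to 5 long noncoding RNAs per direction, and a set of genes fixed for particle exposure. A sentence says so where a gene was chosen otherwise.

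Alternatives were pseudocounts of 1 and 0.1, no filter or a mean of at least 2 FPKM, median-ratio scaling, quantile normalization, robust moderation, array quality weights, each library left out in turn and the replicate number as a block. Sums that add NONCODE transcripts lying at least 50% within a gene on its strand, called locus sums, were added after seeing the data. On simulated data with 14865 genes, the gene fit recovered 49% of genes changed 2-fold and 82% of those changed 4-fold, with 10 false calls. The transcript fit, simulated on 60525 transcripts, recovered 2% and 33%, with 2 false calls. The list test called the list shifted by 1 log2 unit, and before that shift it called 0 of 51 lists. Simulated genes were drawn independently, so this cannot show how often lists of correlated genes are called falsely. The simulated values also held no failed estimates and no fragments moved between transcripts. False calls of genes and transcripts may therefore be more frequent in the real data. Other splits of the 6 real libraries into 3 and 3 called up to 8 genes and 62 transcripts.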

Results

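Lung RNA of mice given PM2.5 through the trachea for 8 weeks was compared with that of mice given saline, with 3 libraries per group. The series sets out to identify long noncoding and circular RNAs after particle exposure, and messenger RNAs, transcripts and long noncoding RNAs were compared here. Values are FPKM, given as mean ± SD of 3 libraries per group, and fold changes are on the log2(FPKM + 0.5) scale, which understates those of low genes. The 3 saline libraries summed to 388125, 364979 and 345089 FPKM and the 3 PM2.5 libraries to 359678, 373635 and 353805. Transcripts listed at 0 numbered 29706 to 31400 in saline libraries and 30749 to 37122 in PM2.5 libraries, with the most in PM2.5 replicate 4, whose estimated depth was the lowest. Across tested genes, which are not independent replicates, log2 values correlated with r of 0.938 to 0.942 between saline libraries. Between PM2.5 libraries r was 0.923 to 0.933, and between groups it was 0.906 to 0.929.

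At the gene level, 11 genes rose and 3 fell with PM2.5. *Cbl*, a ubiquitin ligase that turns off receptor tyrosine kinases, rose from 4.28 ± 0.469 to 17.0 ± 0.740 FPKM. The ubiquitin-conjugating enzyme *Ube2q1* rose from 2.89 ± 0.340 to 11.9 ± 1.37, and the kinase *Map4k3* from 7.77 ± 1.07 to 28.6 ± 3.47. *Gipc1*, an adaptor with a PDZ domain, was 19.2, 18.7 and 20.5 FPKM in the saline libraries and was listed at 0 in all 3 PM2.5 libraries. *Ubald1* fell from 5.07 ± 0.840 to 0.578 ± 0.0718.

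These 14 genes passed among 14865 tested with limma after Benjamini-Hochberg adjustment, and 1707 had an unadjusted p under 0.05, 544 higher and 1163 lower. The log2 fold change of *Cbl* (chromosome 9, 44142976 to 44234049, mm10) was 1.88 ± 0.10 (SE, adjusted p = 0.00876 with limma). Those of *Ube2q1*, *Map4k3*, *Mettl9* and *Tmem245* were 1.87, 1.82, 1.71 and 1.80. The gene *Mettl9* overlaps *Igsf6* on the opposite strand, which these libraries cannot tell apart. *Khnyn* rose from 4.53 ± 0.257 to 9.98 ± 0.624. The low genes *Mir8112* and *Ubn1* rose from 0.0889 ± 0.00218 to 2.40 ± 0.513 and from 0.152 ± 0.142 to 2.37 ± 0.275. *Mir8112* overlaps *Krcc1* on its strand and *Smyd1* on the other. *Ccdc124* was listed at 0 in the 3 saline libraries and was 1.97, 2.63 and 1.38 FPKM in the PM2.5 libraries (adjusted p = 0.0466 with limma). The predicted genes *Gm4617* and *Gm2274*, outside the naming rule and named after their values were seen, complete the 11.

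*Gipc1* (chromosome 8, 83652678 to 83664788) had an adjusted p of 6.08e-05 with limma and passed in all 16 alternatives that tested it. Those alternatives refit the same listed values, so they cannot detect a failed estimate or fragments assigned to an unplaced MERGE transcript. *Kbtbd7* (chromosome 14, 79426511 to 79431039) was 4.89, 5.10 and 4.66 FPKM in saline and was listed at 0 in all 3 PM2.5 libraries (adjusted p = 0.00103 with limma). A NONCODE transcript inside it, NONMMUT021781.2, went the other way, and the locus sum of *Kbtbd7* had a log2 fold change of -0.09 (adjusted p = 0.825 with limma, against 0.000948 to 0.142 in the other alternatives). Of the 14 genes, 8 also passed without saline replicate 2, 3 without saline replicate 3 and 9 without saline replicate 4. Without PM2.5 replicates 2, 3 and 4 the numbers were 8, 9 and 2. *Cbl* was lost without PM2.5 replicate 4 (adjusted p = 0.0594 with limma, range over alternatives 0.00603 to 0.142) and with the replicate block (0.142). With that block 1 of the 14 genes passed, *Gipc1*. The number of all called genes was 9 without saline replicate 3 (6 higher, 3 lower), 26 without saline replicate 4 (12 and 14), 22 without PM2.5 replicate 3 (11 and 11) and 5 without PM2.5 replicate 4 (0 and 5). It was 20 without saline replicate 2 (11 and 9), 15 without PM2.5 replicate 2 (9 and 6) and 9 with a mean of at least 2 FPKM (6 and 3). More genes rose than fell in these settings and without saline replicate 3, but not without saline replicate 4 or PM2.5 replicates 3 and 4.

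*Khnyn*, *Ccdc124* and *Ubn1* were lost on leaving out any 1 of the 6 libraries, with adjusted p of 0.0677 to 0.121, 0.0594 to 0.136 and 0.0628 to 0.127 with limma. *Khnyn* and *Tmem245* were also lost without a filter (0.0539 each), *Ccdc124* without a filter (0.0539) and with a pseudocount of 1 (0.0775), and *Ubn1* without a filter (0.0798), with a pseudocount of 0.1 (0.116) and with robust moderation (0.0510). *Tmem245* was lost without saline replicates 2 and 3 (0.0749 and 0.0707) and PM2.5 replicates 2, 3 and 4 (0.0865, 0.102 and 0.112). *Mir8112* was lost without saline replicates 2, 3 and 4 (0.0664, 0.0707 and 0.0557) and PM2.5 replicate 4 (0.0877), and *Map4k3* without saline replicate 3 (0.0707) and PM2.5 replicates 2 and 4 (0.0643 and 0.0594). Without saline replicate 3 and without PM2.5 replicate 4 the adjusted p of *Ube2q1* was 0.0600 and 0.0745, that of *Mettl9* 0.0600 and 0.0849, and that of *Ubald1* 0.0594 in both.

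Genes next in rank did not pass the threshold. Among them *Pxk* was 0.325 ± 0.359 FPKM in saline and 6.63 ± 1.14 with PM2.5 (adjusted p = 0.0622 with limma), and *Ddx6* was 0.00192 and 4.85 ± 2.31. The lysosomal membrane protein gene *Scarb2* was 37.0 ± 2.81 and 2.90 ± 2.27 (adjusted p = 0.0811 with limma). *Vezf1* was 1.60 ± 0.230 and 0.130 ± 0.107. With locus sums *Pxk* was 4.99 and 13.1 FPKM and passed, with a log2 fold change of 1.31 in place of 3.19 (adjusted p = 0.0486 with limma, against *Pxk* at 0.0330 with a pseudocount of 1, 0.0342 without saline replicate 4 and up to 0.182 in the other alternatives). The log2 fold changes of *Ddx6*, *Scarb2* and *Vezf1* with these sums were 0.40, -0.62 and 0.04, so that of *Vezf1* changed sign. *Ndufa4l2*, which overlaps *Shmt2* on the opposite strand, was 14.0 ± 0.959 and 7.71 ± 0.561, and *Cited2*, a transcriptional coregulator, was 15.6 ± 1.25 and 9.24 ± 0.150. *C1qtnf2* was 7.27 ± 0.541 and 2.88 ± 0.469, and *Rpl27a*, which overlaps *Snora3*, was 87.2 ± 6.97 and 42.4 ± 6.03. *Cyb561* was 28.8 ± 0.811 and 18.5 ± 1.19, and *1810011O10Rik* was 25.6 ± 2.35 and 12.8 ± 1.199.

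Among the fixed gene lists, the plasma cell list, markers of antibody-secreting cells, shifted up. The immunoglobulin heavy chain gene *Igha* rose from 35.4 ± 4.46 to 111 ± 27.0 FPKM, adjusted over the list alone. So did *Ighg1*, from 0.965 ± 0.398 to 72.1 ± 49.0, and the light chain gene *Igkc*, from 122 ± 36.4 to 546 ± 208. *Ighg3* was listed at 0 in saline replicates 2 and 3 and was 0.363 in replicate 4, against 20.1, 8.51 and 34.7 with PM2.5. Of 16 tested members 14 had a positive log2 fold change, with a median of 0.69, and 6 rose adjusted over the list alone (camera adjusted p = 2.09e-07, and adjusted p = 0.663 with an estimated correlation). The members *Ighg2b* and *Derl3* were the others that rose adjusted over the list alone, and the joining chain gene *Jchain* was 9.84 ± 3.18 and 50.8 ± 46.9. These 3 were named after their values were seen. The B cell list did not pass, with a median log2 fold change of -0.38 over 15 members (camera adjusted p = 0.185). The gamma chain genes are close copies of each other, and shared fragments leave single ones uncertain.

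Replication-dependent histone genes shifted down together. The linker histone gene *Hist1h1e* fell from 80.4 ± 23.0 to 16.8 ± 4.59 FPKM and *Hist1h1c* from 48.4 ± 12.04 to 16.6 ± 2.89, adjusted over the list alone. *Hist1h1d* fell from 25.4 ± 3.84 to 6.67 ± 3.22 and *Hist1h3a* from 4.96 ± 1.38 to 0.555 ± 0.480 by the same count. All 12 tested members had a negative log2 fold change, with a median of -1.87, and all 12 fell adjusted over the list alone (camera adjusted p = 3.86e-12, and adjusted p = 0.663 with an estimated correlation). The cell cycle list had a median of -0.08 over 27 members and did not pass (camera adjusted p = 0.347). Histone genes are close copies of each other, which leaves single members uncertain.

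**Figure D1:**
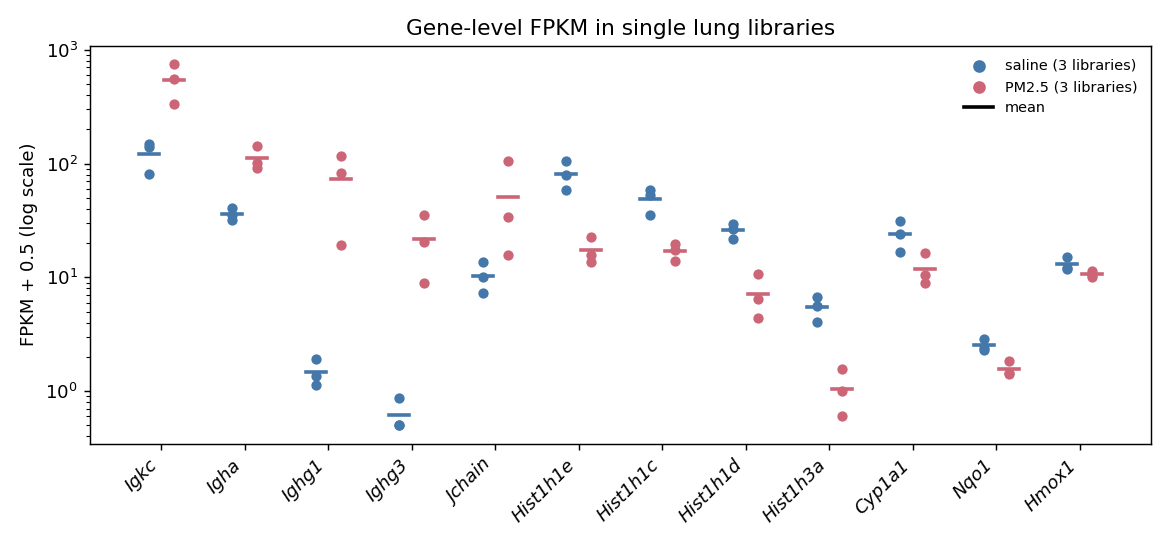
FPKM + 0.5 on a log axis for 12 genes, with 1 point per library and a short line at the mean of the 3 libraries of a group. *Igha* lies between 90.9 and 142 FPKM in PM2.5 libraries and between 31.2 and 40.1 in saline libraries, while *Hist1h1e* lies between 13.2 and 21.996 with PM2.5 and between 58.3 and 104 with saline.

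Genes of extracellular matrix and fibrosis shifted down. *Loxl1*, which crosslinks elastin, fell from 21.4 ± 3.64 to 10.6 ± 0.306 FPKM, the growth factor gene *Tgfb1* from 20.5 ± 3.08 to 12.2 ± 0.374 and *Col3a1* from 106 ± 7.31 to 74.5 ± 9.31, adjusted over the list alone. *Fbn1* was 32.9 ± 2.44 and 25.8 ± 1.497. Fibroblast markers had a similar median log2 fold change of -0.23, with 15 of 17 negative, and did not pass (camera adjusted p = 0.143). Of 28 tested members 22 had a negative log2 fold change, with a median of -0.25, and 3 fell adjusted over the list alone (camera adjusted p = 0.00565, and adjusted p = 0.794 with an estimated correlation). The call was lost without PM2.5 replicate 4 (camera adjusted p = 0.0543). *Col1a1* was 77.4, 86.1 and 4.98 FPKM in the saline libraries and 45.9, 46.0 and 28.8 with PM2.5. Its log2 fold change of 0.26 became -1.04 without saline replicate 4, and neither passed.

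Markers of cell types other than lung epithelium moved both ways. Mesothelial markers shifted up, with *Msln* at 4.74 ± 1.32 FPKM in saline and 9.95 ± 2.92 with PM2.5 and *Upk3b* at 2.10 ± 0.361 and 3.85 ± 1.17. *Rarres2* was 41.4 ± 3.79 and 50.8 ± 3.75. Of 7 members 6 had a positive log2 fold change, with a median of 0.35, and 0 passed adjusted over the list alone, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.00652, and adjusted p = 0.663 with an estimated correlation). The erythroid list shifted up, with a median of 0.17 over 10 members. The heme synthesis gene *Alas2* rose from 45.7 ± 6.32 to 64.3 ± 3.76 and *Fam46c* from 17.5 ± 1.96 to 22.9 ± 0.932, the 2 that rose adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.663 with an estimated correlation). The globin gene *Hbb-bt* was 528 ± 230 and 1146 ± 202; *Hba-a1*, named after its values were seen, was 1141 ± 24.6 and 850.1 ± 663. The erythroid call was lost without saline replicate 3 (camera adjusted p = 0.0536) and without PM2.5 replicate 2 (camera adjusted p = 0.0960).

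Cardiac and skeletal muscle markers, which belong to tissue other than lung parenchyma, shifted down. Whether their source lay inside the lung or in tissue taken with it was not tested. *Myl4* was 85.8 ± 35.0 FPKM in saline and 35.9 ± 40.3 with PM2.5, and *Tnni3* was 13.5 ± 6.41 and 4.21 ± 3.28. PM2.5 replicate 2 stayed near saline, with *Myl4* at 82.2 against 8.87 and 16.7 in PM2.5 replicates 3 and 4, and without it the camera adjusted p was 5.65e-08 for the cardiac and 7.92e-05 for the skeletal list. Adipocyte markers had a median log2 fold change of -1.10 with 8 of 10 negative and did not pass (camera adjusted p = 0.395). Of these, *Fabp4* and *Cidec* are also in the alveolar macrophage list. The 12 cardiac members had a median log2 fold change of -1.68 (camera adjusted p = 0.0149, and adjusted p = 0.855 with an estimated correlation), and 2 had an unadjusted p under 0.05. Of 7 skeletal members, with a median of -1.33, the calcium pump gene *Atp2a1* fell from 1.45 ± 0.531 to 0.293 ± 0.218 adjusted over the list alone (camera adjusted p = 0.0149, and adjusted p = 0.855 with an estimated correlation). Both calls were lost without saline replicate 3 (camera adjusted p = 0.0536 for each) and without PM2.5 replicate 4 (0.107 cardiac, 0.0827 skeletal), and the cardiac call also without PM2.5 replicate 3 (0.123). The skeletal call was also lost with a mean of at least 2 FPKM (0.0527). Oxidative phosphorylation genes, which muscle expresses strongly, shifted down by less, with 22 of 24 negative and a median of -0.21. *Cox6c* was 43.1 ± 3.07 and 35.3 ± 0.142 and *Sdhb* was 33.6 ± 1.202 and 28.7 ± 1.19. In this list 0 members passed adjusted over the list alone and 5 had an unadjusted p under 0.05 with limma (camera adjusted p = 0.00339, and adjusted p = 0.855 with an estimated correlation).

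Markers of NK and cytotoxic cells shifted down, all 11 with a negative log2 fold change and a median of -0.41. *Klrd1* was 5.67 ± 0.611 FPKM in saline and 3.69 ± 0.793 with PM2.5, and the granzyme gene *Gzma* was 16.0 ± 8.90 and 8.84 ± 0.842. T cell markers had a median of -0.19 with 17 of 19 negative, and B cell markers a median of -0.38 with 12 of 15 negative, and neither passed (camera adjusted p = 0.143 and 0.185). Adjusted over the list alone 0 passed with limma and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.0149, and adjusted p = 0.855 with an estimated correlation). The call was lost without saline replicate 2 (camera adjusted p = 0.252) and without PM2.5 replicate 2 (0.0960).

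In the immediate early and heat shock list, the early response genes *Ier2* and *Junb* fell from 25.2 ± 3.13 to 12.5 ± 2.80 and from 17.3 ± 3.69 to 6.12 ± 2.12 FPKM, adjusted over the list alone. The chaperone genes *Hspb1* and *Hsph1* rose from 41.9 ± 7.33 to 92.0 ± 23.1 and from 15.2 ± 5.14 to 35.5 ± 5.81 by the same count. Over the 18 members 3 rose and 6 fell adjusted over the list alone, with a median log2 fold change of -0.69 (camera adjusted p = 0.0498, and adjusted p = 0.951 with an estimated correlation). The sterol regulator *Srebf2* fell from 47.2 ± 1.99 to 34.6 ± 1.69, the 1 of 20 sterol and lipid synthesis genes that passed adjusted over the list alone. That list had a median of -0.24 (camera adjusted p = 0.0181, and adjusted p = 0.855 with an estimated correlation). Of 17 unfolded protein response genes 12 had a positive log2 fold change, with a median of 0.15. *Hsp90b1* was 123 ± 17.6 and 160.2 ± 7.83 while *Atf3* was 5.44 ± 1.27 and 2.65 ± 1.01, and 0 members passed adjusted over the list alone with limma against 6 at an unadjusted p under 0.05 (camera adjusted p = 0.0347, and adjusted p = 0.855 with an estimated correlation).

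These 3 calls depended on single libraries. The immediate early call was lost without saline replicates 2 and 3 (camera adjusted p = 0.419 and 0.0552) and PM2.5 replicate 4 (0.107), and with a pseudocount of 0.1 (0.0647), a mean of at least 2 FPKM (0.110) and array weights (0.112). The sterol call was lost without saline replicates 2 and 3 (0.0802 and 0.187) and PM2.5 replicates 3 and 4 (0.0719 and 0.165). The unfolded protein call was lost without saline replicates 3 and 4 (0.145 and 0.0827) and PM2.5 replicates 3 and 4 (0.138 and 0.0543), and with locus sums (0.0740).

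**Figure D2:**
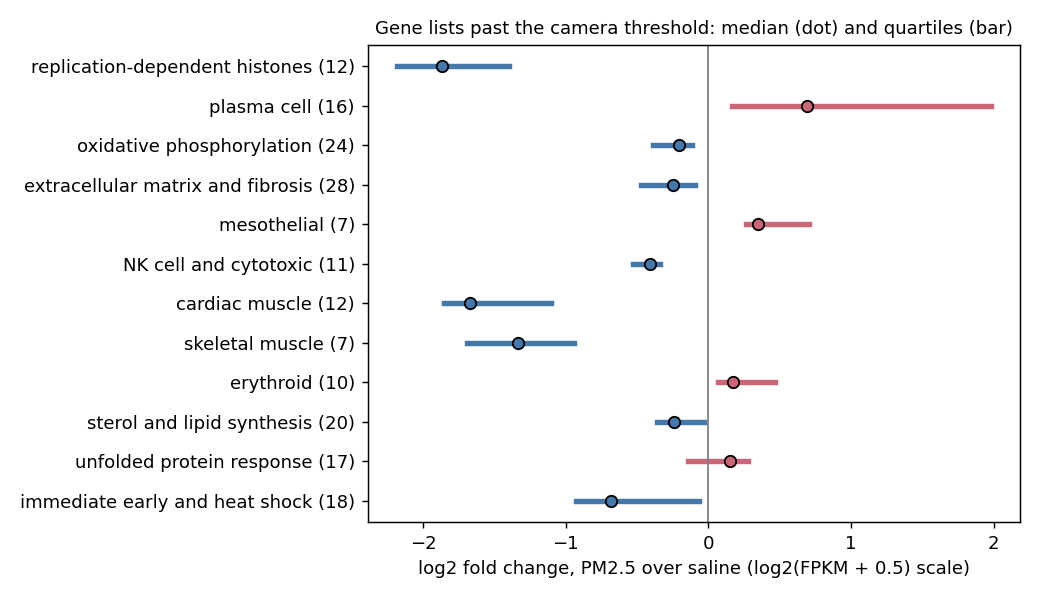
Median log2 fold change, PM2.5 over saline, of the 12 gene lists past the camera threshold, with bars from the lower to the upper quartile over members and the number of members in parentheses. Medians run from -1.87 for replication-dependent histones to 0.69 for the plasma cell list.

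In all, 12 of 51 lists passed the preset-correlation test, 4 up and 8 down. With an estimated correlation 0 passed (smallest adjusted p = 0.663 with an estimated correlation, 2 at an unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.132, 7 at an unadjusted p under 0.05). Over all genes limma called 0 of the 680 list members tested, 115 of which had an unadjusted p under 0.05.

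Genes that respond to particle-borne hydrocarbons and oxidants did not pass. *Cyp1a1*, the main target of the aryl hydrocarbon receptor, was 23.5 ± 7.42 FPKM in saline and 11.4 ± 3.82 with PM2.5 (log2 fold change -1.01 ± 0.31, SE, adjusted p = 0.325 with limma). *Cyp1b1* was 2.10 ± 0.474 and 1.74 ± 0.776. *Nqo1* fell from 2.03 ± 0.297 to 1.06 ± 0.233 adjusted over the 7 aryl hydrocarbon receptor targets alone, but not over the NRF2 targets alone (adjusted p = 0.149), and had an adjusted p of 0.257 with limma over all genes. The heme oxygenase gene *Hmox1* was 12.5 ± 1.93 and 10.2 ± 0.710. The receptor target list had a median of -0.30 (camera adjusted p = 0.275) and the 24 NRF2 targets a median of -0.01 (camera adjusted p = 0.834).

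Inflammatory genes did not pass either. *Il1b* was 4.56 ± 1.42 FPKM in saline and 6.94 ± 1.199 with PM2.5 (adjusted p = 0.427 with limma), *Cxcl1* was 0.659 ± 0.150 and 0.406 ± 0.354, and *Saa3* was 1.01 ± 0.263 and 0.764 ± 0.327. The macrophage genes *Spp1* and *Gpnmb* were 20.7 ± 2.51 and 20.2 ± 1.69, and 2.29 ± 0.392 and 1.83 ± 0.850. *Il6*, *Tnf* and *Ccl2* lay below the filter, with saline means of 0.0759, 0.324 and 0.188 and PM2.5 means of 0.176, 0.422 and 0.306. Neutrophil, alveolar macrophage and interferon-stimulated lists had camera adjusted p of 0.401, 0.669 and 0.922. The neutrophil list tested upward with a mean log2 fold change of 0.16 and a median of -0.02. Of 14 tested p53 targets and senescence genes, *Bbc3*, *Gadd45a* and *Cdkn2b* fell adjusted over the list alone and were named for that (camera adjusted p = 0.173). The surfactant gene *Sftpc* and the club cell gene *Scgb1a1*, named after their values were seen, were 3218 ± 4236 and 3053 ± 3162, and 7282 ± 859 and 4045 ± 1293 (adjusted p = 0.398 for the latter with limma).

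At the transcript level 92 of 60525 transcripts changed, 47 higher and 45 lower, and 5724 had an unadjusted p under 0.05. *Pdgfra*, a receptor of fibroblasts, had transcripts called in both directions. ENSMUST00000168162 fell from 84.9 ± 6.26 to 0.1004 ± 0.00784 FPKM and ENSMUST00000000476 rose from 0.685 ± 0.130 to 89.8 ± 12.6. The sum over *Pdgfra* was 103 ± 7.13 and 117 ± 4.21 (adjusted p = 0.467 with limma). *Brd3*, a chromatin reader, had ENSMUST00000113941 fall from 9.37 ± 0.340 to 0.0343 ± 0.00963 and ENSMUST00000077737 rise from 0.342 ± 0.0626 to 10.6 ± 1.79. ENSMUST00000047737 of *Irf8*, a transcription factor of myeloid cells, was listed at 0 in all 3 PM2.5 libraries and lay between 14.6 and 16.3 in saline, while ENSMUST00000162001 rose from 0.279 ± 0.0619 to 7.83 ± 0.928.

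*Caprin1* was the remaining gene with calls in both directions, with ENSMUST00000028607 falling from 5.29 ± 0.360 to 0.666 ± 0.105 and ENSMUST00000111147 rising from 7.78 ± 0.834 to 34.7 ± 4.80. These 4 genes were named after their values were seen. In each, the called transcripts span much of the same interval, so reassigned fragments cannot be told apart from a change of transcript use. The 57 called Ensembl transcripts belonged to 53 genes, and for 46 of the transcripts the gene sum did not pass. A further 24 calls were MERGE transcripts and 11 were NONCODE transcripts. The count of transcripts was 151 without saline replicate 2, 184 without saline replicate 4, 158 without PM2.5 replicate 2 and 153 without PM2.5 replicate 3. On simulated data the same fit recovered 33% of 4-fold changes, so many such changes go uncalled.

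**Figure D3:**
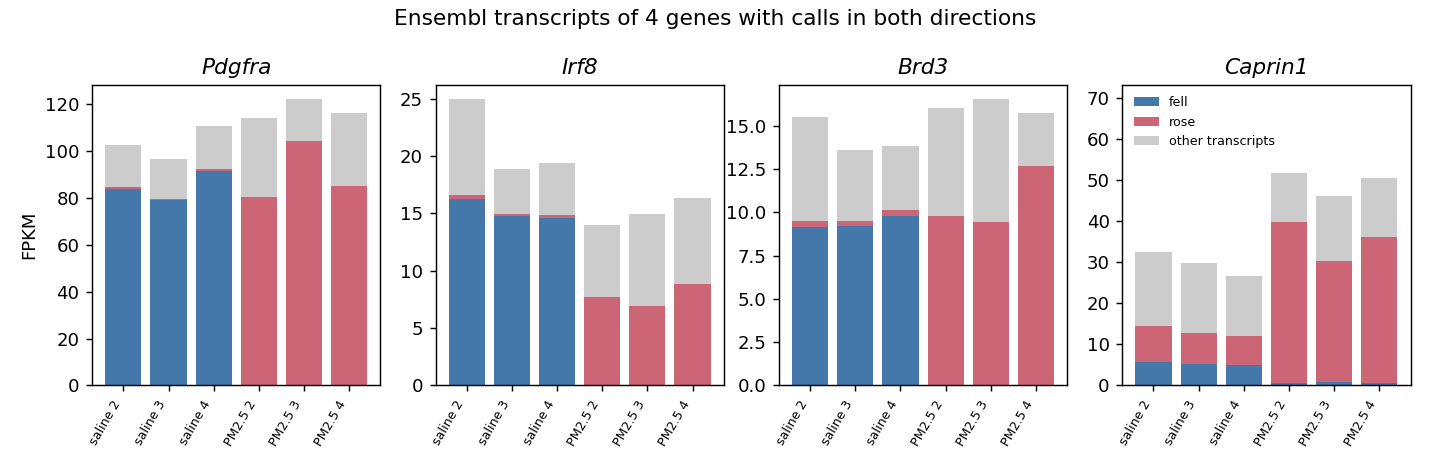
FPKM of Ensembl transcripts of *Pdgfra*, *Irf8*, *Brd3* and *Caprin1* in each of the 6 libraries, stacked from 0, with the transcript that fell in blue, the transcript that rose in red and all others of the gene in grey. In *Pdgfra* the blue part is 84.9 FPKM on average in saline and 0.1004 with PM2.5, and the red part is 0.685 and 89.8.

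Among long noncoding RNAs, 4 NONCODE transcripts rose and 7 fell. NONMMUT154316.1 (chromosome X, 103481269 to 103482898) overlaps *Xist*, which silences an X chromosome in female cells. It rose from 0.114 ± 0.0313 to 83.1 ± 3.96 FPKM (adjusted p = 3.00e-05 with limma). NONMMUT012087.2 (chromosome 11, 101641602 to 101641976, overlapping *Gm24950*) rose from 0.913 ± 1.15 to 134 ± 33.4. NONMMUT050618.2 (chromosome 4, 148953419 to 148954880, overlapping *Casz1*) rose from 0.241 ± 0.0480 to 14.3 ± 0.673. NONMMUT039308.2 (chromosome 2, 118755204 to 118756847, overlapping *A430105I19Rik*) fell from 11.4 ± 2.54 to 0.0967 ± 0.0283.

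NONMMUT021781.2 (within *Kbtbd7*) rose from 0.170 ± 0.0394 to 4.76 ± 0.611 FPKM. NONMMUT012873.2 (overlapping *Mfsd11*) fell from 6.23 ± 0.672 to 0.104 ± 0.00868, and NONMMUT002115.2 (overlapping *St8sia4*) from 2.9999 ± 0.407 to 0.0128 ± 0.00687. NONMMUT005178.2 (overlapping *Rnf217*) fell from 3.86 ± 0.954 to 0.141 ± 0.0313. NONMMUT124662.1, which fell, was 2.65, 2.85 and 2.88 in saline, 0.0548 in PM2.5 replicate 3 and listed at 0 in PM2.5 replicates 2 and 4. It overlaps *Cnot3* and *Prpf31* on its strand and *Tfpt* on the other, from which it cannot be told apart without strand. The *Cnot3* transcript ENSMUST00000206331 went the other way, from 0.0391 ± 0.0168 to 2.87 ± 0.479. NONMMUT003822.2 (overlapping *Dcaf8*) was 0.488 ± 0.147 and 2.504 ± 0.295 and did not pass. Each of these transcripts overlaps an annotated gene on its own strand, and fragments of the 2 can be shared. The FPKM change summed over the locus, divided by that of the transcript, was 0.108 for NONMMUT124662.1, 0.286 for NONMMUT002115.2 and -0.064 for NONMMUT021781.2. These calls therefore cannot be told apart from fragments moved within the locus. For the other named long noncoding transcripts that passed, the ratio was 0.579 to 2.05.

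The 11 calls came from 14793 tested long noncoding transcripts, of which 1285 had an unadjusted p under 0.05, 786 higher and 499 lower. Adjusted over the list alone, 4 rose and 6 fell. NONMMUT005178.2 was lost with a mean of at least 2 FPKM (adjusted p = 0.0918 with limma). The count was 6 with that filter, 23 without saline replicate 2, 29 without saline replicate 4, 21 without PM2.5 replicate 2 and 23 without PM2.5 replicate 3. NONMMUT012087.2 was lost without saline replicates 3 and 4 (adjusted p = 0.0565 and 0.0517 with limma) and without PM2.5 replicates 2, 3 and 4 (0.0569, 0.0706 and 0.0809). NONMMUT154316.1 passed in all 15 alternatives that tested it.

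Of 92 Ensembl genes classed as long noncoding, limma called 0 over all genes, 10 had an unadjusted p under 0.05, and *Xist* rose adjusted over the list alone. *Xist* was 6.51 ± 3.33 FPKM in saline and 55.2 ± 12.9 with PM2.5 (adjusted p = 0.106 with limma over all genes). Y-linked *Kdm5d* was at most 0.00752 in any library, *Ddx3y* at most 0.0439 and *Eif2s3y* at most 0.0291. *Xist* was 8.90, 2.71 and 7.92 in saline replicates 2, 3 and 4, so these values show no difference in sex between the groups. *Malat1* was 0.454 in saline replicate 4 and listed at 0 in the other 5 libraries, so it lay below the filter. A value listed at 0 can be a failed estimate, so these values do not show that *Malat1* was not expressed. *Neat1* and *Uty* were not analysed here. The RNA component of RNase MRP, *Rmrp*, was 4280 ± 2597 and 854 ± 272 (adjusted p = 0.228 with limma) and fell adjusted over the list of named long noncoding RNAs alone. That list did not pass (median -0.26 over 16 members, camera adjusted p = 0.233).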

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

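Locus sums were the test chosen only after the result was seen. The settings gave 9 to 16 genes outside the replicate block and the left-out libraries, against 14 with the planned settings, and the sums gave 16 genes and 11 lists. A mean of at least 2 FPKM gave 9 genes and 6 long noncoding RNAs, from fewer genes and transcripts tested. Leaving out each library gave 5 to 26 genes, 127 to 184 transcripts, 11 to 29 long noncoding RNAs and 8 to 12 lists, the lowest gene count without PM2.5 replicate 4 and the highest without saline replicate 4. An unadjusted p with a doubling or halving gave 1557 transcripts, a setting that drops the adjustment and adds a fold limit at once. Camera with an estimated correlation and fry each gave 0 lists. With the replicate block there were 1 gene, 5 transcripts, 1 long noncoding RNA and 13 lists. Libraries with the same number did not deviate together (r across genes of -0.03, -0.03 and 0.05), so the numbers are not taken to pair samples. The log2 fold change of *Spp1*, -0.03, became 0.0126 with median-ratio scaling and ranged from -0.11 to 0.0582 with libraries left out, above 0 without saline replicate 3 and, at 0.04, without PM2.5 replicate 2. That of *Cyp1b1*, -0.26, ranged from -0.50 to 0.0224, the latter without PM2.5 replicate 4, that of *Col1a1*, 0.26, ranged from -1.04 without saline replicate 4 to 0.95 without saline replicate 3, and that of *Vezf1*, -1.75, became 0.0427 with locus sums; the cause was not tested. Of all values of single named genes under alternatives, 1343 kept direction and side of the threshold, 70 lost the call, 11 gained one and 6 changed direction. Scaling moved the median log2 fold change of all genes from -0.03 to 0.01 (median-ratio) and 0.02 (quantile). The histone, plasma cell, mesothelial and oxidative phosphorylation lists passed in all 15 alternatives that kept the preset correlation. Count models (edgeR and DESeq2) were planned for counts only and were not run, and robust moderation gives no list test.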

Other observations

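The tests of transcripts within a locus, of proliferation, of structural RNAs, of B cells, of antibody-secreting cells and of immunoglobulin constant genes were chosen only after the result was seen, while the test of short genes and the splits of the libraries were not.

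Immunoglobulin variable segments, outside the fixed lists, were chosen after seeing the constant genes. Of 103 tested segments 87 were higher with PM2.5, with a median log2 fold change of 0.91, and 32 were higher in every PM2.5 library than in every saline library, where chance gives 10% over both directions together. Over all genes limma called 0 of them and 25 had an unadjusted p under 0.05 (camera p = 2.43e-17, and p = 0.0293 with an estimated correlation). The kappa light chain segments had a median of 1.08 over 61 and the heavy chain segments 0.91 over 39, while the 3 lambda segments had 0.20. Of the constant genes *Ighd* was 16.8, 11.4 and 14.8 FPKM in saline and 8.50, 4.76 and 13.98 with PM2.5, against the direction of *Igkc* and *Igha*. Among genes of the histone clusters, 57 of 58 tested were lower and 47 were lower in every PM2.5 library than in every saline library, 48 had an unadjusted p under 0.05, and limma called 0 over all genes.

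Of 6826 tested MERGE loci 10 passed, among them MERGE.33021, listed at 0 in saline and at 47.9, 29.9 and 44.9 FPKM with PM2.5, and MERGE.30623, at 19.1, 30.9 and 38.0 in saline and listed at 0 with PM2.5. The unplaced locus MERGE.21433 did not pass (adjusted p = 0.423 with limma). Its transcript MERGE.21433.4 was 1776, 1368 and 1948 FPKM in the PM2.5 libraries and listed at 0 in all 3 saline libraries. MERGE.21433.5 was 1258 in saline replicate 2 and MERGE.21433.3 was 1743 in PM2.5 replicate 2, each listed at 0 in the other 5 libraries. At the *Xist* locus, locus sums gave 11.3 FPKM in saline and 139 with PM2.5 (adjusted p = 0.00256 with limma, against 0.0594 to 0.233 in the other alternatives). The housekeeping gene *Gapdh* had a mean of 1.63 FPKM in saline and 1.40 with PM2.5 in its Ensembl transcripts, against 747 and 748 for *Actb*. So low a value for *Gapdh* can be a failed estimate, or its fragments may have been counted in MERGE transcripts. Other gene sums listed at or near 0 share this limit.

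With 10 possible splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split gave 14 genes, 92 transcripts, 11 long noncoding RNAs and 12 lists, and the highest other split gave 8, 62, 9 and 18. As many were reached by 1 split each for genes, transcripts and long noncoding RNAs, the real one, and by 4 for lists. The real split gave the smallest camera p of the 10 for the histone, plasma cell, extracellular matrix, mesothelial and erythroid lists, and for the other 7 lists at least 1 other split gave one as small.

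Most called Ensembl transcripts belonged to genes whose sums did not pass. If fragments had only moved between transcripts of similar length at a locus, the locus sum would change far less than the transcript. FPKM are scaled to transcript length, so fragments moved between transcripts of unlike length can change the sum too. The median ratio of the locus change to the transcript change was 0.473 (95% bootstrap interval 0.341 to 0.809, 67 transcripts), with 34 below 0.5 and 33 at or above it, so that moved fragments and a change of the locus cannot be told apart for the set, and MERGE transcripts without a position keep it open. Transcripts listed at 0 in one group and at 5 FPKM or more in each library of the other numbered 10 in the real split, and the highest other split also gave 10. A change of splicing or promoter use with PM2.5 stays open and untested.

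Lower histone transcripts were set against less proliferation, a lower yield of RNAs without a poly(A) tail and a lower yield of short genes. The cell cycle list had a median log2 fold change of -0.0822 (-0.18 to -0.03), 40 structural RNAs -0.0347 (-0.13 to 0.09) and other protein-coding genes spanning under 1500 bases -0.26 (-0.30 to -0.16), against -1.87 for the histones. None of these medians comes near the histone change, which argues against each as the whole cause. Short genes were nevertheless lower than all genes, whose median was -0.03. The intervals resample genes, so they do not measure the spread between libraries. Single structural RNAs had SE of up to 3.83 (*Rn7s1*), which makes their median the weakest of these tests. Structural RNAs went both ways (SD over members 1.01), and *Rmrp* at -2.20 and *Rnu3b4* at -4.80 were among 3 that were lower at an unadjusted p under 0.05, so a loss limited to some RNAs without a tail stays open. GC content could not be tested without a genome and may contribute, and a difference between the exposures remains a hypothesis.

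Higher immunoglobulin transcripts were set against more B cells, more antibody-secreting cells and fragments moved between constant genes. B cell markers without immunoglobulin genes had a median of -0.38 (-0.45 to -0.31, 13 genes), so they showed no rise. With an estimated correlation of 0.71 for the B cell list, an interval over markers understates the spread between libraries. More B cells are therefore not excluded. FPKM summed over 13 constant genes were 218, 133 and 222 in saline and 542, 796 and 1041 with PM2.5, a ratio of 4.16, which argues against moved fragments. Plasma cell markers without immunoglobulin genes had a median of 0.46 (0.12 to 1.10, 8 genes), above 0 but with an interval on both sides of 0.5, so more antibody-secreting cells may account for the pattern but cannot be told apart from more transcript per cell. Exposure to PM2.5 stays open, as does any difference between mice in immune status.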
